A study of Homo sapiens with 6 samples.

How the data were processed

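RNA was measured on 6 Affymetrix arrays, 1 per sample, from Jurkat cells, an established human T-cell acute lymphoblastic leukaemia line. Per the labels' protocols, cells grown in medium with 10% serum were starved of serum for 90 min. They were then either left unstimulated or given CXCL12 at 100 ng/ml for 15 min. Total RNA was extracted with Trizol and labelled with a whole-transcript kit. The sample titles call the 3 samples of each group biological replicates. Whether these were separate cultures is not stated, so p-values of single probe sets measure the spread between these samples, which may be partly technical. The groups are called untreated (n = 3) and CXCL12 (n = 3) here.

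The deposited table holds 1 value per probe set and array on a log2 scale. RMA (robust multi-array averaging, which subtracts background, normalizes between arrays and summarises the probes of a set) and the Transcriptome Analysis Console are named in the submitters' processing notes. Their versions, settings and the genome build are not given in the sources used here. The table has 21448 probe sets, no missing values, and values from 1.99 to 13.1. The sorted values of the arrays differed by at most 0.29, so the distributions were close but not identical. The array scanner files were not used here, so detection calls, probe-level signal and scan batches were not examined. The number of arrays limits the precision.

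Probe sets were named from the platform annotation supplied with the data, which can be old. Of the 21448 probe sets, 17709 had 1 gene symbol, 0 had several and 3739 are unnamed here. The symbols of all 17709 named probe sets occurred in the RefSeq gene table of assembly GRCh38.p14, which was used only for names, so no coordinates are given. There were 20 symbols with more than 1 probe set.

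The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 6 arrays, no covariates) on the deposited log2 values as they stand. Probe sets with a mean below the 25th percentile (a log2 mean of 4.44) were left out as dim, which left 16086 probe sets and 13455 named genes. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Changes are log2 differences, CXCL12 minus untreated, with limma's moderated standard error (SE) or 95% interval. Values per group are the mean ± SD of the log2 signal with n = 3.

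For gene lists, 28 lists were fixed for this cell type and treatment, with markers of other cell types among them. Each gene was represented by its probe set with the highest mean, and members called measured are those with a named probe set that was not left out as dim. Lists were tested with limma's camera, which asks whether a list's genes differ from all other genes. Its inter-gene correlation was preset to 0.01, and its p-values were adjusted over the 28 lists. With the preset correlation, these p-values rest mainly on the spread between genes, not on that between the arrays. With a correlation estimated per list, 0 of the 28 lists passed. Members also received an adjusted p over the list alone.

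The genes named were chosen by rule. The rule took 12 genes per direction, starting with those past the threshold whose CXCL12 arrays lay beyond all untreated arrays and ordered by size. The remaining places went to the smallest unadjusted p. It added 14 genes in any case (CXCR4, ACKR3, FOS, JUN, JUNB, EGR1, EGR3, IER2, NR4A1, DUSP1, DUSP2, MYC, CD69 and NFKBIA) and the 4 members with the smallest p of each list past its threshold, of the immediate early list and of the CXCL12 receptor list. Other members named with a list were chosen after their values were seen.

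The groups, the tests, the lists, the rule and the alternatives were set before the data were examined, except where stated. The alternatives were other filters on dim probe sets (none, or the lower 50%), renormalization (quantile, median centring or cyclic loess), a replicate block, array weights, a trended robust prior, other thresholds, a correlation estimated per list, the fry test, averaging of probe sets, and leaving out each array in turn. Both groups carry replicate numbers 1 to 3. No pairing is stated for these numbers, so they were not taken as pairs, a choice made before the data were examined. Deviations of same-numbered arrays from their group means correlated across probe sets at -0.19, -0.11 and 0.11, which cannot exclude a pairing.

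The fit was tested on simulated data: 20 sets of 6 arrays drawn around the real untreated means with limma's moderated variances, 200 of the 16086 probe sets changed. It recovered 41.2% of changes of 0.5 on the log2 scale (1.41-fold), 94.2% of changes of 0.75 (1.68-fold) and 100% of changes of 1 (2-fold), and 6.67% of all calls were false. These shares hold for 200 changed probe sets. With few real changes the adjusted threshold is harder to reach. The list test called a list shifted by 0.2 in every member in 20 of 20 simulations with 2 other lists called, and made 1 call in 20 simulations with no shifted list. All simulated values were drawn independently, without correlation between genes or an array that stands apart. In the real data the estimated correlation of the histone list was 0.22, so the simulated rate of false calls need not hold there. Figures were drawn with matplotlib 3.10.9.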

Results

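Gene expression was compared between serum-starved Jurkat cells that received CXCL12 for 15 min and cells that did not. CXCL12 is a chemokine that signals through the G protein-coupled receptor CXCR4. The question, as the series states it, was which transcripts differ after stimulation. There were 3 untreated and 3 CXCL12 arrays. Median log2 signals per array ran from 6.18 to 6.22. Correlations between arrays over the 16086 tested probe sets ran from 0.979 to 0.991. Untreated replicate 1 stood apart: its mean correlation with the other arrays was 0.982, against 0.987 to 0.989 for the others, and it lay at -27.8 on the first principal component (38.6% of the variance), where the other arrays lay between -5.84 and 11.6.

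The transcript of EGR1, a zinc-finger transcription factor of the immediate early class, rose 3.96-fold with CXCL12. Its log2 signal was 5.99 ± 0.11 in untreated and 7.97 ± 0.17 in CXCL12 arrays (SD, n = 3 each), a change of 1.98 (SE 0.13, limma adjusted p = 4.52e-05). CD69, a surface receptor that appears early on activated lymphocytes, rose 2.53-fold, from 5.90 ± 0.36 to 7.24 ± 0.17, a change of 1.34 (SE 0.17, limma adjusted p = 0.0394). Both were higher in 3 of 3 CXCL12 arrays than in every untreated array. These were the 2 probe sets (TC0500008785.hg.1 and TC1200009876.hg.1) among 16086 that passed the adjusted threshold, and 0 passed in the downward direction, where 323 had an unadjusted limma p under 0.05. EGR1 passed in each of the fits that left out 1 array. CD69 passed without untreated replicate 1 or 3, but not without untreated replicate 2 (adjusted p = 0.0674) or CXCL12 replicate 1, 2 or 3 (adjusted p of 0.342, 0.0687 and 0.532).

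The other 10 genes at the upper end did not pass after adjustment over all probe sets, and each was higher in every CXCL12 array than in every untreated array. As these genes were chosen by their p, which favours such separation, it adds no support. GPR3, a receptor that raises cyclic AMP, had 1.92 times the untreated signal (log2 change 0.94, SE 0.14, limma adjusted p = 0.0865). SGK1, a serum- and glucocorticoid-regulated kinase, was at 1.78 times (log2 change 0.83, limma adjusted p = 0.172). The transcription factors CSRNP1, JUN and KLF10 had changes of 0.70, 0.69 and 0.71. HSPH1, a chaperone of the HSP110 family, had a change of 0.66. GLIPR1 changed by 0.72, ADM, which encodes the peptide adrenomedullin, by 0.73, and LIMA1, an actin-binding protein, by 0.55. IFNA13 changed by 0.58 from an untreated level of 4.32, below the mean of 4.44 that marked probe sets as dim, and it belongs to a family of near-identical interferon genes, so its identity is uncertain. For the 8 genes after SGK1 in order of p, the limma adjusted p ran from 0.506 to 0.829.

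At the lower end, 12 genes were listed by their unadjusted p and none passed, with limma adjusted p from 0.655 to 0.927. They had log2 changes between -0.42 and -0.72, and each was lower in every CXCL12 array than in every untreated array. Choosing genes by p favours such separation, so it adds no support. NUP133, a nuclear pore scaffold protein, had -0.72, AXIN2, a Wnt pathway scaffold, -0.64, SCRT1, a zinc-finger repressor, -0.59, EPOP, a Polycomb-associated protein, -0.57, and SLC22A5, a carnitine transporter, -0.51. TDRD9 had -0.63, TCP10L -0.52, RUFY3 -0.54, PLAC1 -0.59, RWDD2A -0.59, B3GAT1 -0.71 and CDC42EP3, a CDC42 effector, -0.42. The signal of NUP133 in CXCL12 arrays, 4.48 ± 0.29 (SD, n = 3), lay close to the limit of 4.44 for dim probe sets. The CXCL12 means of AXIN2, TCP10L, PLAC1, CDC42EP3, TDRD9, SCRT1 and EPOP, from 4.71 to 4.97, were also near it. Those of B3GAT1, RUFY3, RWDD2A and SLC22A5 were higher, from 5.065 to 5.79. The stricter alternative filter on dim probe sets removed all 12 genes, so their changes were not tested under it.

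**Figure D1:**
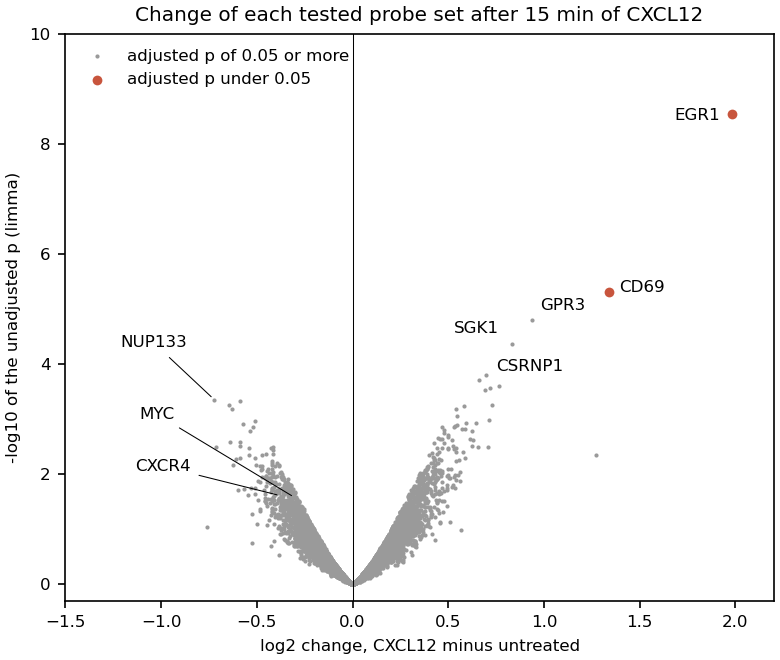
Log2 change with CXCL12 (x axis, CXCL12 minus untreated) against the negative log10 of limma's unadjusted p (y axis) for the 16086 tested probe sets, 3 arrays per group. EGR1 (1.98) and CD69 (1.34) are the 2 red points past the adjusted threshold of 0.05, and grey points did not pass it.

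In the main fit, counts over the transcriptome were close to those expected by chance. An unadjusted limma p under 0.05 was reached by 761 probe sets, against 804 expected by chance, of which 438 were higher and 323 lower with CXCL12. This count depended on the fit. It was 1047 with array weights, 1014 without CXCL12 replicate 2 and 548 without CXCL12 replicate 3, each over 16086 probe sets. A count near 804 therefore does not show that few transcripts changed. At p under 0.001 there were 17 against 16 expected, 13 of them higher. The arrays of the groups did not overlap for 1534 probe sets (9.54%), where chance gives 10%. For 14455 probe sets (89.9%), the 95% interval lay within a 1.5-fold change either way.

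The immediate early genes, which are transcribed within minutes of a signal without new protein synthesis, were higher as a list with CXCL12. Of 39 measured members, 33 had a positive change and 6 a negative one, with a median log2 change of 0.17 (quartiles 0.05 and 0.29). The list passed camera with an adjusted p of 6.12e-10, and the call was lost with an estimated correlation (adjusted p = 0.0868). That estimate was 0.014, close to the preset 0.01, so the size of the correlation alone does not account for the lost call. EGR1 was the 1 member that passed over all genes tested. Adjusted over the list alone, 7 rose, 0 fell and 32 did not pass. The 7 were EGR1, SGK1 (adjusted p over the list 0.000836), CSRNP1 (0.00204), JUN (0.00292), KLF10 (0.00809), IER3 (0.0252) and IER2 (0.029), all from limma. The mean change of the list, relative to the untreated mean, was 0.28, 0.18 and 0.26 in CXCL12 replicates 1, 2 and 3, and between -0.05 and 0.04 in the untreated arrays. Leaving EGR1 out, an alternative added after seeing the data, gave a median of 0.16 (adjusted p = 7.52e-08).

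Other members named in advance did not pass over all genes or over the list alone. FOS, the partner of JUN in the AP-1 transcription factor, had 6.46 ± 0.05 in untreated and 6.39 ± 0.04 in CXCL12 arrays (SD, n = 3 each), a log2 change of -0.07 with a 95% interval from -0.32 to 0.17. JUNB had a change of 0.23 (95% interval -0.15 to 0.62), NR4A1 0.26 (-0.04 to 0.55), DUSP2 0.23 (-0.07 to 0.53), DUSP1 0.05 (-0.31 to 0.41) and EGR3 0.10 (-0.19 to 0.40). Single arrays moved these values: JUNB was 0.06 without untreated replicate 1, 0.39 without untreated replicate 2 and 0.10 without CXCL12 replicate 3. NR4A1 was 0.13 without CXCL12 replicate 1 and DUSP2 0.12 without CXCL12 replicate 3. FOS was -0.05 without untreated replicate 3. DUSP1 ran from -0.09 (without CXCL12 replicate 3) to 0.20 (without CXCL12 replicate 2), with -0.08, 0.13 and 0.10 without untreated replicates 1, 2 and 3. EGR3 ran from -0.03 (without CXCL12 replicate 2) to 0.19 (without CXCL12 replicate 1). MYC, a growth-promoting transcription factor, had -0.30 (-0.56 to -0.04), with a limma adjusted p of 0.996 over all probe sets and 0.104 over the list alone. KLF4, NR4A2 and NR4A3 were left out as dim, with mean log2 signals of 4.44, 3.95 and 4.08 in untreated and 4.39, 4.02 and 4.42 in CXCL12 arrays, and were not tested. No probe set was named here for EGR2, BTG1 or BTG2.

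**Figure D2:**
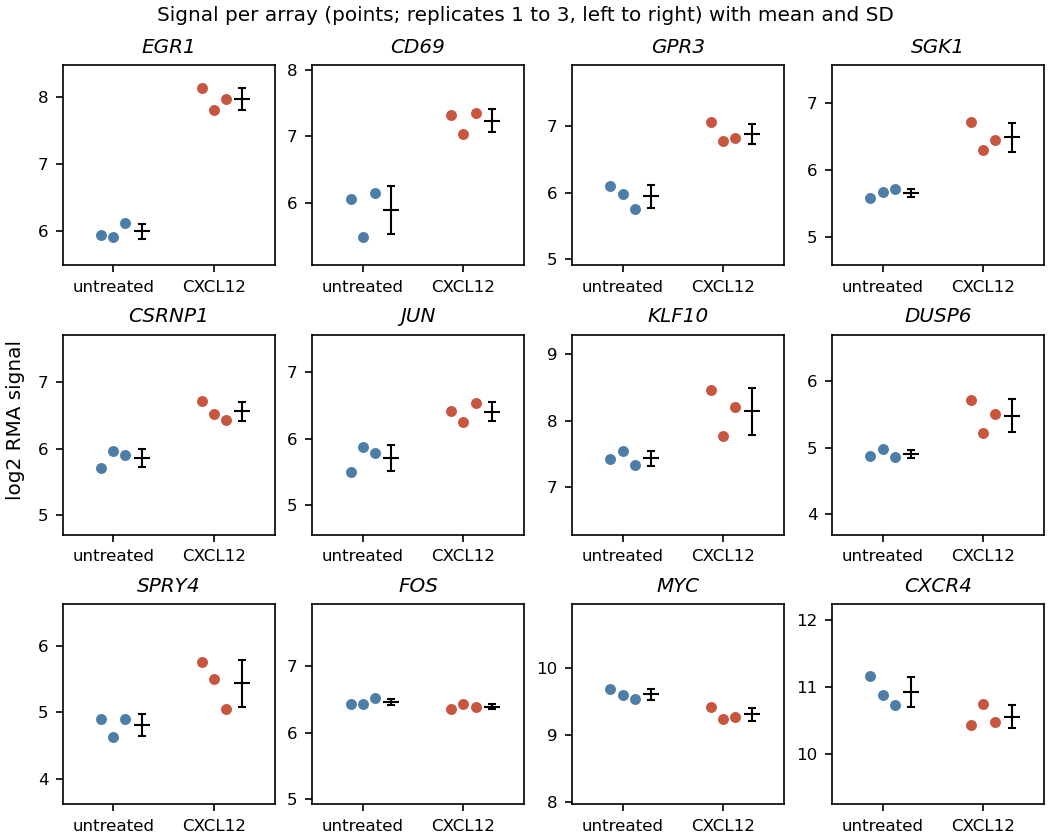
Log2 RMA signal (y axis, each panel spanning 3 log2 units) of 12 genes in the untreated (blue) and CXCL12 (red) arrays, with the mean and SD of 3 arrays in black. EGR1 and CD69 lay higher in all CXCL12 arrays, FOS differed by -0.07, and MYC and CXCR4 had lower means with CXCL12.

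Feedback regulators of the ERK kinase pathway also passed the list test in the upward direction, with overlapping arrays. Relative to the untreated mean, the list lay at 0.22, 0.08 and 0.20 in CXCL12 replicates 1, 2 and 3 and at -0.02, 0.10 and -0.08 in the untreated ones. Of 15 measured members, 10 had a positive and 5 a negative change, with a median log2 change of 0.24. The list is broad, and whether each member acts on ERK was not checked. It also holds DUSP10 (0.32), DUSP8 (-0.11), DUSP16 (-0.17) and PHLDB2 (-0.20). The camera adjusted p was 0.0209, and the call was lost with an estimated correlation (adjusted p = 0.609). No member passed over all genes tested. Adjusted over the list alone, 2 rose and 0 fell: DUSP6, a phosphatase that inactivates ERK, with 0.57 (limma adjusted p over the list 0.0226), and SPRY4, an inhibitor of receptor-to-ERK signalling, with 0.63 (0.0232). ETV5, an ETS transcription factor downstream of ERK, had 0.54 (0.0645), or 0.35 without CXCL12 replicate 1, and DUSP5, a nuclear ERK phosphatase, 0.31 (0.0879). The list's call was also lost without untreated replicate 3 (median 0.135, adjusted p = 0.211) and without CXCL12 replicate 3 (median 0.143, adjusted p = 0.0597). It was lost as well with the lower 50% of probe sets left out (adjusted p = 0.343), a filter that removed DUSP6, SPRY4 and DUSP5.

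Replication-dependent histone genes passed the list test in the downward direction, by a small amount and with overlapping arrays. Of 45 measured members, 34 had a negative and 11 a positive change, with a median log2 change of -0.06. The camera adjusted p was 0.046, and with an estimated correlation, here 0.22, it was adjusted p = 0.646. No member passed over all genes or over the list alone. The members with the smallest p were H1-2 (-0.24), H4C4 (-0.36), H2BC7 (-0.26) and H4C12 (-0.20), each with a 95% interval that included 0. With each array left out in turn, H4C4 ran from -0.58 (without untreated replicate 2) to -0.14 (without untreated replicate 1), and H2BC7 reached -0.15 and H1-2 -0.16 without CXCL12 replicate 3. Histone genes are near-identical copies whose probes can be shared, so values of single members are uncertain. Relative to the untreated mean, the list lay at -0.16 in CXCL12 replicate 3 and at -0.03 and -0.02 in replicates 1 and 2, against -0.03, -0.03 and 0.06 in untreated replicates 1, 2 and 3. CXCL12 replicates 1 and 2 were thus within the untreated range. Without CXCL12 replicate 3 the median was -0.02 (adjusted p = 0.615), and without untreated replicate 3 it was -0.03 (adjusted p = 0.448).

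The receptor and its signalling chain were examined at the transcript level. CXCR4 had 10.9 ± 0.23 in untreated and 10.6 ± 0.17 in CXCL12 arrays (SD, n = 3 each), a log2 change of -0.37 (95% interval -0.69 to -0.06) that did not pass (limma adjusted p = 0.996 over all probe sets, 0.458 over the list alone). Its arrays overlapped, with CXCL12 replicate 2 at 10.75 and untreated replicate 3 at 10.73. The CXCR4 change was -0.25 without untreated replicate 1 and -0.47 without untreated replicate 3. ACKR3, another receptor for CXCL12, had a change of -0.15 (-0.50 to 0.20) at an untreated level of 4.89, close to the limit for dim probe sets. The change was -0.00275 without untreated replicate 1 and -0.33 without untreated replicate 2. Of the 37 measured genes of CXCL12 receptor signalling, 17 had a positive and 20 a negative change, and 0 passed over all genes or over the list alone (camera adjusted p = 0.389). TIAM1, an activator of the GTPase RAC1, had -0.43 (-0.28 without CXCL12 replicate 2), PIK3CG, a G protein-coupled PI3-kinase, 0.23, and RGS16, a regulator of G protein signalling, 0.24.

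T cell activation genes did not shift as a list (median 0.01, camera adjusted p = 0.389). CD69 was the 1 member of 15 measured that passed, both over all genes and over the list alone. A further 9 listed genes were left out as dim, among them IL2, IL2RA and IFNG, with untreated mean log2 signals of 2.67, 3.68 and 2.88 and CXCL12 means of 2.63, 3.64 and 2.92. These examples were chosen after their values were seen. Targets of NF-kB, an inflammatory transcription factor, had a median of -0.02 over 18 members, with 5 positive and 13 negative changes and 0 passing (camera adjusted p = 0.389). NFKBIA, the NF-kB inhibitor that NF-kB itself induces, had -0.16 (95% interval -0.48 to 0.16), with -0.02 without CXCL12 replicate 3, -0.30 without CXCL12 replicate 2 and -0.11 without untreated replicate 2.

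**Figure D3:**
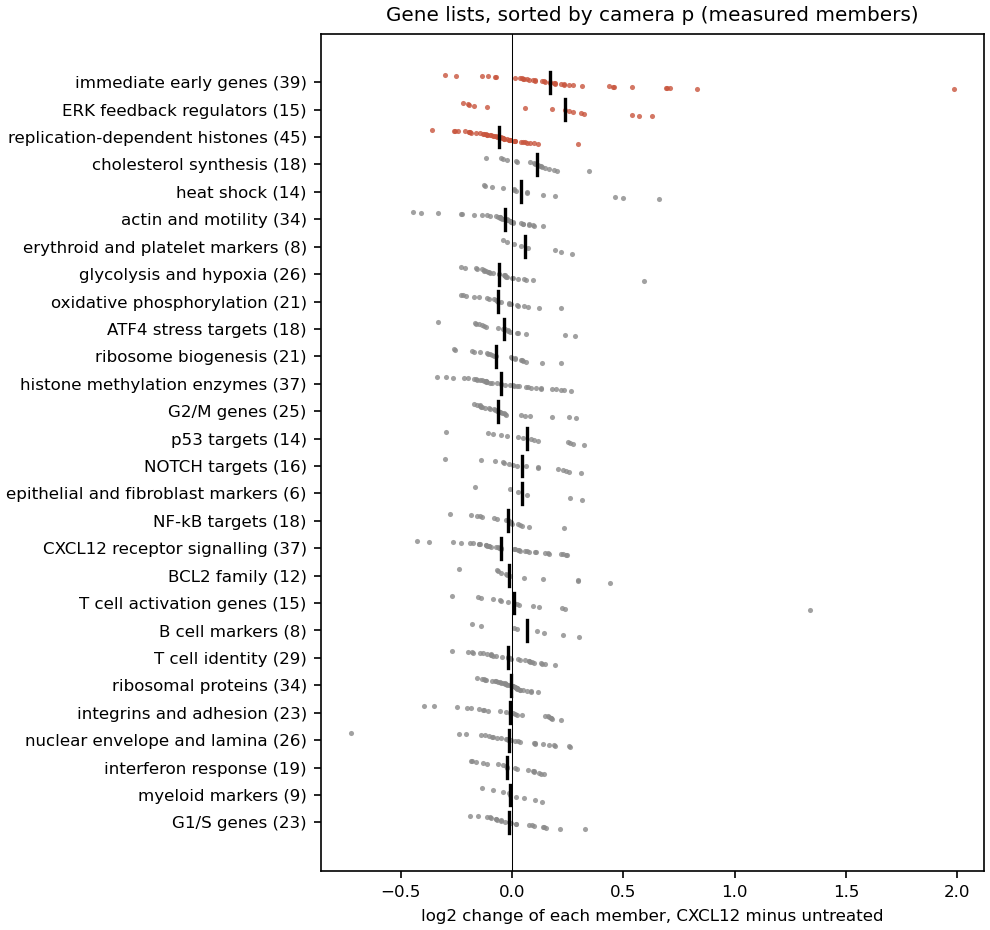
Log2 change of each measured member (points, x axis) of the 28 gene lists, sorted by camera p, with the median as a black bar and the number of measured members in brackets. Red lists passed the adjusted threshold of 0.05: immediate early genes (median 0.17), ERK feedback regulators (0.24) and replication-dependent histones (-0.06). With an estimated correlation none of these passed (adjusted p = 0.0868, 0.609 and 0.646).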

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

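The count of 2 probe sets became 1 with no filter on dim probe sets, with median centring and with cyclic loess, 3 with the lower 50% left out and with the trended robust prior (EGR1, CD69 and GPR3), and 4 with array weights (the same genes and SGK1). GPR3 passed in 3 of 14 refits (adjusted p from 0.0102 to 0.581). The count became 34 under an unadjusted p with a 1.5-fold change (22 higher, 12 lower). Under an unadjusted p with a 2-fold change it was 3, all higher: EGR1, CD69 and the unnamed TC1300009332.hg.1. With the adjusted threshold, the count ran from 1 to 2 when each array was left out. EGR1 passed in each of its 14 refits (limma adjusted p from 3.1e-06 to 0.00158, log2 change from 1.90 to 2.07). CD69 passed in 7 of 14 (adjusted p from 0.00872 to 0.532, change from 1.14 to 1.47). The replicate block gave 2 probe sets, the same genes, and 2 lists, the histone list being lost (-0.06, adjusted p = 0.0568). The labels state no pairing by replicate number. Deviations of untreated replicate 1 correlated best with those of CXCL12 replicate 2 (0.28), but such correlations cannot exclude a pairing. The count of 3 gene lists became 4 with quantile normalization again and with cyclic loess, where cholesterol synthesis and heat shock entered and histones dropped out. It was 3 with the lower 50% left out, where these lists took the places of histones and ERK feedback. It became 5 with array weights, 0 with a correlation estimated per list and 0 with fry, and ran from 1 to 5 when each array was left out (1 without untreated or CXCL12 replicate 3, 5 without untreated replicate 1). The fit without EGR1 was chosen after the results were seen. The immediate early list kept its direction in its 17 settings, the 1 without EGR1 included, and passed in 15, failing with an estimated correlation and with fry (median 0.169 in both, adjusted p of 0.0868 and 0.0775). It ran from 0.125 to 0.221 when each array was left out. The ERK feedback list failed with the lower 50% left out (median 0.148) and under an estimated correlation and fry (0.238), and ran from 0.135 to 0.324 when each array was left out. The histone list failed with no filter (-0.0474), the lower 50% left out (-0.0521), quantile normalization again (-0.0495), cyclic loess (-0.0467), the replicate block, an estimated correlation and fry (-0.0587), and ran from -0.0937 to -0.0228 when each array was left out. Among named genes, signs turned 3 times, none of them past the threshold: DUSP1 without untreated replicate 1 (-0.0801) or CXCL12 replicate 3 (-0.0932) and EGR3 without CXCL12 replicate 2 (-0.0253), with highest values of 0.201 for DUSP1 and 0.190 for EGR3 when other arrays were left out. No scaling moved the median change of all probe sets beyond -0.02. The causes of these changes were not tested. With 3 arrays a side, the median half-width of a 95% interval was 0.29 on the log2 scale (1.23-fold), which limits what smaller changes can show.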

Other observations

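Other gene groups had small changes. Heat shock genes had a median log2 change of 0.04 over 14 members (camera adjusted p = 0.0692). Adjusted over the list alone, 2 rose: HSPH1 (0.66, limma adjusted p over the list 0.00272) and DNAJB1, a co-chaperone of HSP70 (0.50, 0.0242). HSPA1A, an inducible HSP70 with a near-identical copy, had 0.46 (0.104), while the other 11 lay between -0.13 and 0.19. The list passed in 6 of 16 alternatives (adjusted p from 0.0187 to 0.609): quantile normalization again (0.0258), cyclic loess (0.0242), the lower 50% left out (0.0187), array weights (0.0355), without untreated replicate 1 (0.0297) and without CXCL12 replicate 2 (0.0453). It did not pass with fry (0.433) or at adjusted p = 0.609 with an estimated correlation. Its median was 0.00555 without untreated replicate 2, 0.09 without untreated replicate 3 and 0.12 without CXCL12 replicate 2. Cholesterol synthesis genes had a median of 0.11, with 14 of 18 positive (adjusted p = 0.0692). They passed in 3 of 16 alternatives: quantile normalization again (median 0.15, adjusted p = 0.00718), cyclic loess (0.14, 0.0115) and the lower 50% left out (0.11, 0.0187). They did not pass with fry (0.435) or at adjusted p = 0.609 with an estimated correlation. The median was 0.03 without untreated replicate 1 (adjusted p = 0.363) and 0.07 without CXCL12 replicate 1 (adjusted p = 0.367). STARD4, a sterol transfer protein, had 0.35 and did not pass (limma adjusted p over the list 0.232). In the glycolysis and hypoxia list (median -0.06, adjusted p = 0.353), SLC2A3, a glucose transporter, was the 1 of 26 members that rose when adjusted over the list alone (0.59, 0.0304). That list passed in the downward direction without untreated replicate 1 (adjusted p = 0.0047) and passed with array weights, both with the preset correlation. With all arrays it had adjusted p = 0.646 with an estimated correlation.

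Actin and motility genes had a median of -0.03 over 34 members (camera adjusted p = 0.168), with the kinase ROCK1 at -0.44, the actin nucleation promoter WASL at -0.33 and RDX, a membrane-actin linker, at -0.41. None of the 34 passed over all genes or over the list alone. Integrins and adhesion had -0.01 (0.552), nuclear envelope and lamina -0.01 (0.789, with NUP133 at -0.72 the 1 member that fell over the list alone) and histone methylation enzymes -0.05 (0.389, with KMT2A at -0.34, which did not pass over the list alone). The adjusted p was 0.381 for oxidative phosphorylation and for ATF4 stress targets, and 0.389 for ribosome biogenesis, G2/M genes, p53 targets, NOTCH targets and the BCL2 family. It was 0.472 for T cell identity, 0.525 for ribosomal proteins, 0.789 for interferon response and 0.999 for G1/S genes. Among markers of other cells it was 0.413 for B cell, 0.999 for myeloid, 0.31 for erythroid and platelet and 0.389 for epithelial and fibroblast markers, of which 8 of 12, 9 of 14, 8 of 12 and 6 of 12 listed genes were measured. Median, mean and test differed in sign for the BCL2 family (median -0.02, mean 0.06, upward), myeloid markers (median -0.01, mean 0.00175, upward) and G1/S genes (median -0.02, mean 0.01, downward).

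In the patterns weighed here, the tests on untreated replicate 1, EGR1, heat shock, scaling and dim probe sets were chosen after the results were seen. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 2 probe sets against at most 0 in the others, so 1 of 10 splits gave as many. It gave 3 lists, and 2 of 10 splits gave as many, the highest other being 3. The unadjusted camera p of the immediate early list, with the preset correlation, was 2.19e-11 in the real split. It ran from 0.00232 to 0.487 in the others, with several values under 0.05. Each other split keeps 2 arrays of a group together, so part of the difference between groups remains and these splits are no clean reference for chance. The split of untreated replicates 1 and 2 with CXCL12 replicate 2 against the rest gave 1663 probe sets with p under 0.05, against 761 in the real split, which points to a structure among the arrays other than the groups.

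Without untreated replicate 1 the immediate early list had a median change of 0.125 (camera adjusted p = 3.14e-08), and without EGR1 0.158 (7.52e-08). Both p-values used the preset correlation and rest mainly on the spread between genes, so they cannot settle the part of single arrays. Relative to the untreated mean, the list lay at 0.28, 0.18 and 0.26 in CXCL12 replicates 1, 2 and 3. It lay at -0.05, 0.04 and 0.004 in untreated replicates 1, 2 and 3. All untreated arrays thus lay below all CXCL12 arrays, which argues against untreated replicate 1 as the only source. With all arrays and members the call was lost with fry (0.0775) and with an estimated correlation (adjusted p = 0.0868). One hypothesis is that heat or handling during stimulation, and not the chemokine, may raise such genes. The heat shock list had a camera adjusted p of 0.0692 and a mean change of 0.12 with a 95% interval over members from -0.02 to 0.27. That interval treats the 14 members as independent and measures the spread between genes, not between arrays. Relative to the untreated mean, the list lay at 0.17, 0.04 and 0.16 in CXCL12 replicates 1, 2 and 3. It lay at 0.02, -0.08 and 0.06 in untreated replicates 1, 2 and 3, so the arrays overlapped. The list passed in 6 of 16 alternatives but not with fry (0.433) or an estimated correlation (adjusted p = 0.609), which leaves this hypothesis open. The labels mention no vehicle-treated arm. A response to CXCL12, the difference that the design names, also stays open and was not separated from it.

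Untreated replicate 1 deviated from the mean of the other arrays with an SD of 0.275 on the log2 scale, against 0.175 to 0.205 for the others, and 24 of its probe sets lay over 1 log2 unit away, against at most 3 on another array. A difference in scaling or distribution left in the deposited values is argued against. With the distributions made identical by quantile normalization again, the SD stayed at 0.275, against 0.173 to 0.205 for the others. That step hardly moved any array, as the deposited values were already normalized. Scaling before the submitters' normalization was not tested. Noise of dim probe sets is argued against by an SD of 0.262 in the brightest tested probe sets (the top 20%), where the others had 0.134 to 0.169. Relative to the mean of the other arrays, SNX2 lay at 1.35 and LRRCC1 at 1.07, and ZRANB3 at -1.16 and KBTBD2 at -1.14, all chosen after their values were seen. EGR1 lay lowest, at -1.25, but the other arrays include the CXCL12 arrays, where it was higher. These deviations and the count of 24 can thus hold part of the difference between groups. RNA quality, base composition of the probes and the state of that culture were not tested, and no biological explanation was tested.

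The FOS probe set differed by -0.07 between groups while that of EGR1 rose by 1.98, and the difference between these changes was not tested. Whether the FOS probe set responds on this array was not examined. An unnamed probe set, TC0400008985.hg.1, chosen after its values were seen, had a change of 0.76 (limma adjusted p = 0.535). Another, TC1300009332.hg.1, rose at least 2-fold with an unadjusted limma p under 0.05 but did not pass the adjusted threshold.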
